A study of Homo sapiens and Pan troglodytes with 11 samples.

How the data were processed

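Transcripts of a chosen set of genes and guide barcodes were measured by HyPR-seq, a probe-based single-cell RNA assay, in neurons made from human and chimpanzee induced pluripotent stem cells under CRISPR interference. In CRISPR interference a nuclease-dead Cas9 with a repressor is led by a guide RNA to a chosen site, whose activity it lowers. Per the labels' protocols, dissociated neurons were fixed, permeabilised, hybridised overnight with pooled probes, ligated to a readout oligonucleotide and put into droplets with barcoded beads for amplification. Each deposited table holds counts of unique molecular identifiers (UMIs), with 1 row per cell barcode and 1 column per gene probe or guide barcode, per the file headers. All values were whole numbers, with 0 exceptions in every library. The submitters' processing notes name fastp, UMI-tools, Bowtie and SAMtools and the hg38 build. Their versions and roles, and the rule by which cell barcodes were kept, are not given in the sources used here. Probe sequences were not analysed here, so how well each probe matches chimpanzee transcripts was not examined.

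Species came from the labels: 6 libraries of the human line WTC11 and 5 of the chimpanzee line C3649, in screen replicates 1 and 2. The labels do not say that libraries of 1 screen replicate are separate cultures, and each species is 1 line. P-values therefore measure the spread between these libraries, which may be technical, and not the spread between individuals of a species. Every pair of libraries of 1 species and panel differed far beyond counting noise (chi-square per degree of freedom at least 185), so each was counted once. The columns showed a pair of gene panels, called panel 1 (10 genes, 7 libraries) and panel 2 (21 genes, 4 libraries) here, with 7 genes on both. All 28 guide barcodes (7 named Brainbar, 21 named SplintRbar) were in every table. Their names show neither a target region nor a control, and a map from barcode to guide was not used here, so each barcode was its own class. The list of preset pairs of human accelerated region and gene could therefore not be tested.

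For the species comparison, UMIs were summed per gene and library over all deposited cells, without guide barcodes. The 7 genes of both panels were fitted over all 11 libraries relative to their own total, panel 1 genes over its 7 libraries, and panel 2 genes over its 4. The test was edgeR's quasi-likelihood test with TMM factors and Benjamini-Hochberg adjustment over all 24 genes at 0.05. It shares the estimate of spread between the genes of a fit, so SEs and p-values do not rest on each gene's own spread alone. In the fit of panel 2 the sharing was nearly complete, with SEs of 0.17 to 0.18 for all genes. Its SEs and p-values thus show almost nothing of a gene's own spread between libraries. Genes needed 10 UMIs in at least 5 libraries. For panel 2 genes, with 4 libraries, that minimum was asked of all 4, a departure from the written rule that it cannot otherwise meet. Normalized UMIs are per 1000 effective UMIs of the genes in the fit, so a rise in an abundant gene lowers the shares of the others. A cell was assigned to the guide barcode with most UMIs if it had at least 5 and made up at least 70% of the cell's guide UMIs. Guide effects compared the cells of a barcode with all other assigned cells of the same library, with the library as a block. A class needed 5 cells and a barcode 3 libraries, and genes needed 10 UMIs in at least 6 classes. The interaction of species and barcode was tested in 1 fit over both species. The number of assigned cells per barcode was tested between species without TMM. Median UMIs per cell and cells per library were compared by two-sided exact permutation tests over 462 splits.

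The dispersion was the common estimate passed to edgeR's earlier quasi-likelihood method (legacy=TRUE). This choice was made after first results were seen. The newer default takes its dispersion from the top 10% of genes, too few in panels of this size, and could not be fitted to the cells per barcode over all libraries. Both were tested on simulated counts, and results by the newer default are given among the alternatives. The simulated counts had a set dispersion of 0.02 for the species comparison and 0.01 for the guide fits. In the guide fits each size of change had 15 to 20 simulated genes. The shares called hold for that spread and do not give the power for genes that vary more between libraries. For the species comparison of 24 genes, the method used called 92.5% of genes simulated with a log2 change of 1 and 95% of those with -1, 35% and 45% at 0.5 and -0.5, and 1.88% of unchanged genes (2.5% by the newer default). For the guide fits of 7 genes, it called 100% (human) and 100% (chimpanzee) of changes of 1, 100% and 90% of changes of -1, 62.5% and 72.2% at 0.5, 80% and 80% at -0.5, and 0.726% and 0.831% of unchanged genes (1.81% and 2.16% by the newer default).

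Each panel and species was also fitted with all barcodes in 1 model, each barcode against the mean of the others, with the library as a block and at least 2 libraries per barcode. These joint fits were added after the panels were seen, because most genes of panel 2 cannot enter a fit that needs 3 libraries. A rule for assignment by background was also added then: at least 20 UMIs and at least 10 times the library's background. In all, guide effects were examined under 5 assignment rules and in pooled and joint fits. Other choices were fixed before the data were examined. Their alternatives were DESeq2 size factors or tests, totals without TMM, GAPDH as the library size, no count filter, cells with at least 100 UMIs, equal weight per cell with limma, screen replicate as a block or alone, sums per screen replicate, other class minimums and leaving out each library. No doublet caller was run, and cells with several guide barcodes above background are counted in the text. The named genes are those of the species comparison, apart from 1 that was fitted and is not reported here, and the guide and gene pairs that passed or, where fewer than 5 passed, the 5 with the smallest p. Of the gene lists fixed beforehand, the housekeeping list had 1 of its 20 genes on a panel and the study's target genes 3 of 3. The lists of excitatory neuron (24 genes), pluripotent (10), progenitor or cycling (10), glial (10), inhibitory neuron (8) and peripheral neuron (5) markers had 0, so no other cell type could be looked for.

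Depth ranged from 420217 to 1818477 gene UMIs per library. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. Correlations across barcodes were tested with 100000 permutations. Gene positions are from GENCODE 29 on GRCh38. Software was R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.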

Results

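Human accelerated regions are stretches of conserved DNA that changed unusually fast on the human lineage, and the series asks what they do in 2-week-old excitatory neurons. Neurons came from WTC11, a human induced pluripotent stem cell line, and C3649, a chimpanzee line. The 11 libraries held 41950 cells, 20278 in 6 human and 21672 in 5 chimpanzee libraries, with 10647638 gene UMIs and 25759018 guide-barcode UMIs. Cells per library ran from 1199 to 7562, and the median cell had between 126 and 567.5 gene UMIs. Screen replicate 1 held human 1 to 3 and chimpanzee 1 and 2, all with the 10 genes of panel 1. In screen replicate 2, human 6 and chimpanzee 5 had panel 1, while human 4 and 5 and chimpanzee 3 and 4 had the 21 genes of panel 2. RHOB or PUM2 was the most abundant gene of every panel 1 library (22.0% to 31.5% of gene UMIs), and GAPDH of every panel 2 library (45.2% to 67.9%).

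The 24 genes lie at 10 places on GRCh38. ARHGAP5, AKAP6, NPAS3, BAZ1A and PSMA6 lie on chromosome 14 between 32.1 and 35.3 Mb, with NPAS3 itself at 32934933 to 33804176. TENM3 and DCTD are neighbours on chromosome 4 (182.1 to 182.9 Mb), and LAPTM4A, PUM2 and RHOB on chromosome 2 (20.0 to 20.4 Mb), where GLI2 also lies (120.7 to 121.0 Mb). BTG1, SOCS2 and PLXNC1 lie on chromosome 12 between 92.1 and 94.3 Mb, and GAPDH at 6.5 Mb. NRSN2, SRXN1 and SCRT2 are on chromosome 20 (0.3 to 0.7 Mb) and ONECUT2 on chromosome 18 (57.4 to 57.5 Mb). Chromosome 3 holds BHLHE40 (4979116 to 4985323) and DAZL, PLCL2 and TBC1D5 (16.6 to 18.4 Mb). All 24 are annotated as protein-coding.

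How far the genes differ between neurons of the species was asked first. Ratios are of probe UMIs relative to the genes of the fit, and how well probes match chimpanzee transcripts was not examined. BHLHE40, SOCS2, ONECUT2, BTG1 and GLI2 were measured in 2 libraries per species, all of screen replicate 2. Human neurons had more UMIs of BHLHE40, a transcriptional repressor, at a log2 ratio of 1.86 ± 0.18 (SE). They had more of SOCS2, a suppressor of cytokine signalling, at 1.21 ± 0.17. They also had more ONECUT2, a homeobox transcription factor (1.08 ± 0.17), and more AKAP6, an anchor of protein kinase A (0.98 ± 0.25). Chimpanzee neurons had more BTG1, an antiproliferative factor (-1.75 ± 0.18), and more GLI2, a transcription factor of Hedgehog signalling (-1.64 ± 0.18). NPAS3, a neuronal transcription factor (-0.60 ± 0.09), BAZ1A, a subunit of chromatin remodellers (-0.59 ± 0.18), and TENM3, a teneurin of synaptic contacts (-0.59 ± 0.06), were also higher in chimpanzee. By edgeR's quasi-likelihood test 14 of the 24 genes differed, 9 higher and 5 lower in human neurons. At an unadjusted level of 0.05 there were 15, and DESeq2 called 15.

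The 5 remaining genes higher in human neurons were PLXNC1, a semaphorin receptor (0.83 ± 0.17), SRXN1, an antioxidant enzyme (0.75 ± 0.17), ARHGAP5 (0.72 ± 0.10), DAZL (0.71 ± 0.17) and PSMA6, a proteasome subunit (0.51 ± 0.12). Adjusted p by edgeR ranged from 6.40e-12 for BHLHE40 to 0.0104 for BAZ1A. The value of BHLHE40 rests on 2 libraries per species and on a spread shared by the genes of panel 2. TENM3 stood at 140 ± 7.78 normalized UMIs per 1000 in human and 211 ± 8.45 in chimpanzee libraries (SD, n = 6 and 5), and ARHGAP5 at 113 ± 10.2 and 68.9 ± 9.86. NPAS3 stood at 51.2 ± 4.70 and 86.6 ± 14.9 per 1000 UMIs of panel 1 (n = 4 and 3). Over all libraries, AKAP6 stood at 315 ± 53.8 and 160 ± 63.1. BAZ1A, at 64.1 ± 18.3 and 96.6 ± 11.7, was the only called gene whose libraries overlapped between the species. BTG1 stood at 11.4 ± 1.17 and 38.6 ± 3.12 (n = 2 and 2), and BHLHE40 at 6.29 ± 0.457 and 1.73 ± 0.210. DAZL, a germ cell gene, had 2.01 ± 0.00582 and 1.23 ± 0.122, the lowest of panel 2 in either species (next GLI2 at 3.10 in human and BHLHE40 at 1.73 in chimpanzee).

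**Figure D1:**
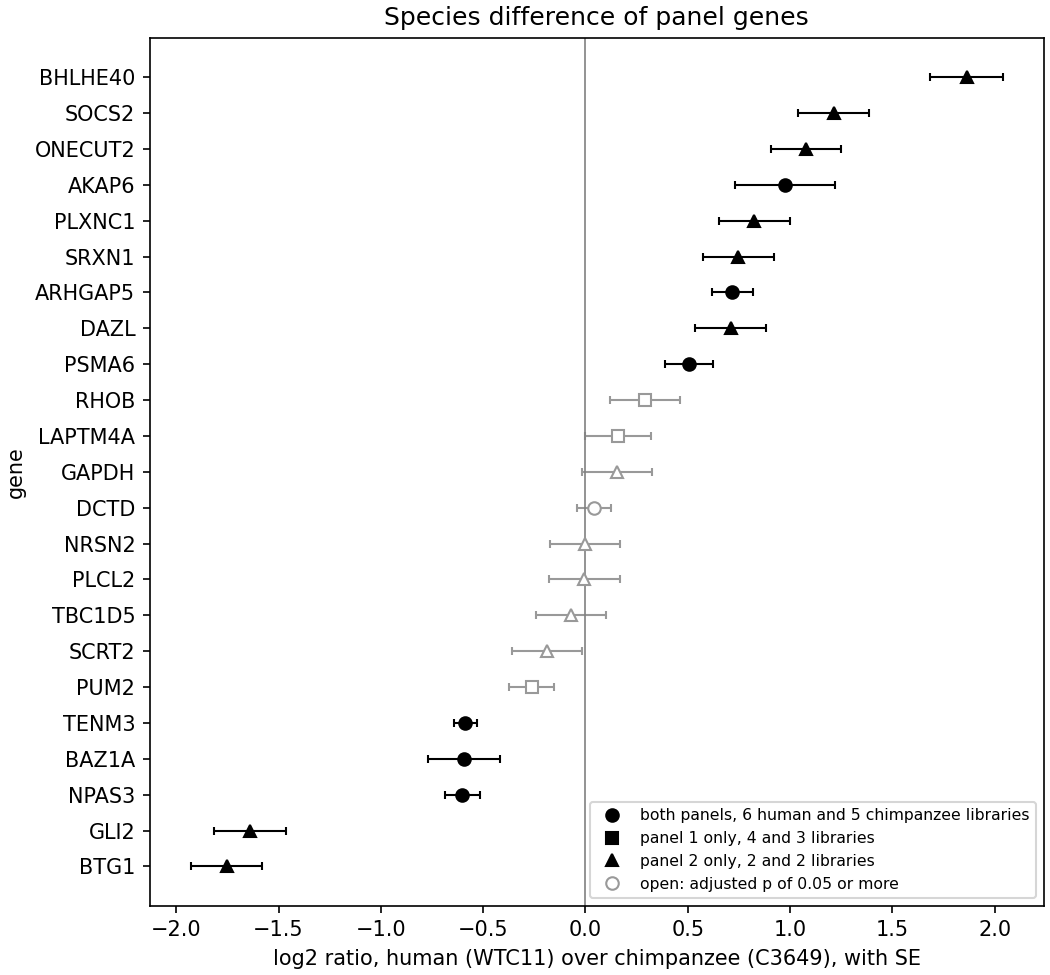
Log2 ratio of human over chimpanzee libraries for each gene reported (points, with SE as bars), from the fit that held most libraries for the gene. Filled points are the 14 genes with an adjusted p under 0.05, from BHLHE40 at 1.86 to BTG1 at -1.75.

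The 3 genes listed beforehand as the study's targets were measured. NPAS3 fell by 0.60 and SOCS2 rose by 1.21 in human against chimpanzee neurons, while PUM2, an RNA-binding translational repressor, had a log2 ratio of -0.26 ± 0.11 and an adjusted p of 0.0511. Adjusted over the list alone, 3 of 3 passed against 2 of 3 over all genes, and as the study chose this list on these or related samples, that is not independent evidence. GAPDH, a glycolytic enzyme and the 1 housekeeping gene measured, had a ratio of 0.15 ± 0.17. It stood at 815 per 1000 in human 4 and 360 in human 5, against 528 ± 43.0 in chimpanzee libraries. The SEs of all genes fitted in panel 2 alone were nearly equal (0.17 to 0.18), as the test shares the spread between genes. That of GAPDH thus does not show the gap between human 4 and human 5. Without human 4 the ratio of GAPDH was -0.53, and without human 5 it had the opposite sign (0.63). These genes did not pass either: RHOB 0.29 ± 0.17 (which passed in 4 alternatives, with 0.53 the highest ratio and 0.0104 the lowest adjusted p), LAPTM4A 0.16 ± 0.16, DCTD 0.04 ± 0.09, NRSN2 0.00 ± 0.17, PLCL2 0.00 ± 0.17, TBC1D5 -0.07 ± 0.17 and SCRT2 -0.19 ± 0.17.

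Within each panel, relative to all genes of that panel, AKAP6 was higher in human (0.51 ± 0.11 in panel 1 and 0.97 ± 0.17 in panel 2). NPAS3 (-0.76 ± 0.13 and -1.25 ± 0.17), BAZ1A (-1.04 ± 0.13 and -0.74 ± 0.17) and TENM3 (-0.84 ± 0.12 and -1.07 ± 0.17) were lower, all with adjusted p under 0.05. ARHGAP5 passed in panel 1 (0.52 ± 0.11) but not in panel 2 (0.23 ± 0.17, adjusted p = 0.291). PSMA6 passed in neither, with 0.27 ± 0.15 (adjusted p = 0.121) and 0.03 ± 0.17 (adjusted p = 0.957). DCTD had -0.25 ± 0.12 (adjusted p = 0.0785) and -0.41 ± 0.17 (adjusted p = 0.0356). In screen replicate 1 alone 5 of 10 genes passed, and in screen replicate 2 alone 14 of 21. The genes of panel 2 alone rest on 2 libraries per species, and with GAPDH as the library size 0 of 20 genes passed by edgeR (3 at an unadjusted level of 0.05, no other tool run). Compared with totals of the same 4 libraries, log2 ratios moved by only 0.07 to 0.15 (ARHGAP5 from 0.23 to 0.36, PSMA6 from 0.03 to 0.10), and BHLHE40 had 1.96 ± 0.70 and BTG1 -1.63 ± 0.69. SEs were 0.67 to 0.70 in place of 0.17 to 0.18, so the 13 calls of these genes with totals ended through lost precision and not through smaller ratios.

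**Figure D2:**
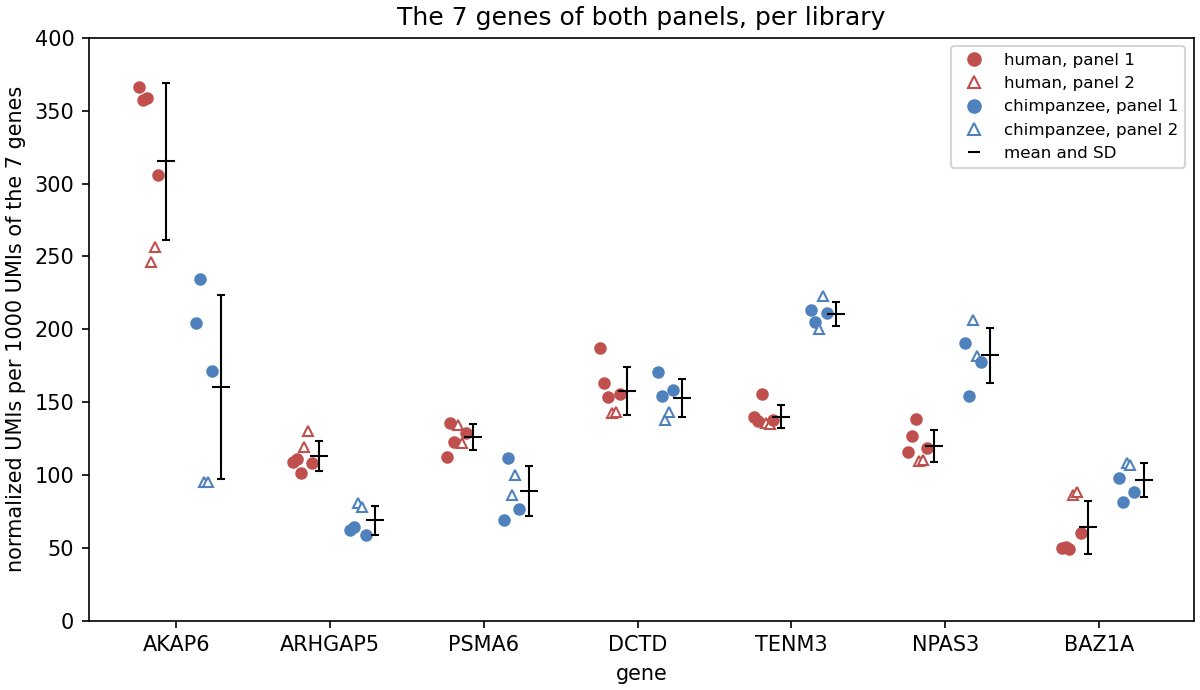
Normalized UMIs of the 7 genes of both panels in each of the 11 libraries (points), per 1000 UMIs of those genes, with the mean and SD of each species beside them. TENM3 and NPAS3 are higher in each chimpanzee library than in any human one, and AKAP6 is lower in the panel 2 libraries of both species.

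Whether depth differed between the species was also asked, and no difference was found by the test used. The mean log2 of median gene UMIs per cell was 7.83 ± 0.56 in human and 7.90 ± 0.79 in chimpanzee libraries, a difference of -0.07 (two-sided exact permutation test, p = 0.879). Within screen replicate 1 the exact p was 0.8 and within screen replicate 2 it was 0.9. Human libraries had 3380 ± 2484 cells and chimpanzee libraries 4334 ± 1367 (exact permutation p = 0.474). In screen replicate 1 the difference was -1530 cells (exact p = 0.1, the smallest that 10 splits allow), and in screen replicate 2 it was 81 (exact p = 0.9).

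Which cells carried which guide barcode decides what the screen can show. In 9 libraries between 11.7% and 32.9% of cells had 1 barcode assigned, for example 24.7% of human 1 (95% interval 22.4% to 27.1%) and 32.9% of chimpanzee 2 (31.2% to 34.6%). In human 6, 3 of 7562 cells were assigned (0.0397%, 0.00818% to 0.116%), and in chimpanzee 5, 6 of 5512 (0.109%, 0.0400% to 0.237%). Guide UMIs of a cell in these libraries were spread over the barcodes much as in the library as a whole. The guide comparisons therefore rest on 5 human and 4 chimpanzee libraries and on 2503 human and 3169 chimpanzee assigned cells. Cells with several barcodes above background numbered between 199 and 1956 in the other libraries. Such cells were more frequent in screen replicate 1, from 1082 of 3107 in chimpanzee 2 to 1275 of 1707 in human 3. In the panel 2 libraries they ran from 199 of 4621 in human 5 to 1109 of 5825 in chimpanzee 3.

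**Figure D3:**
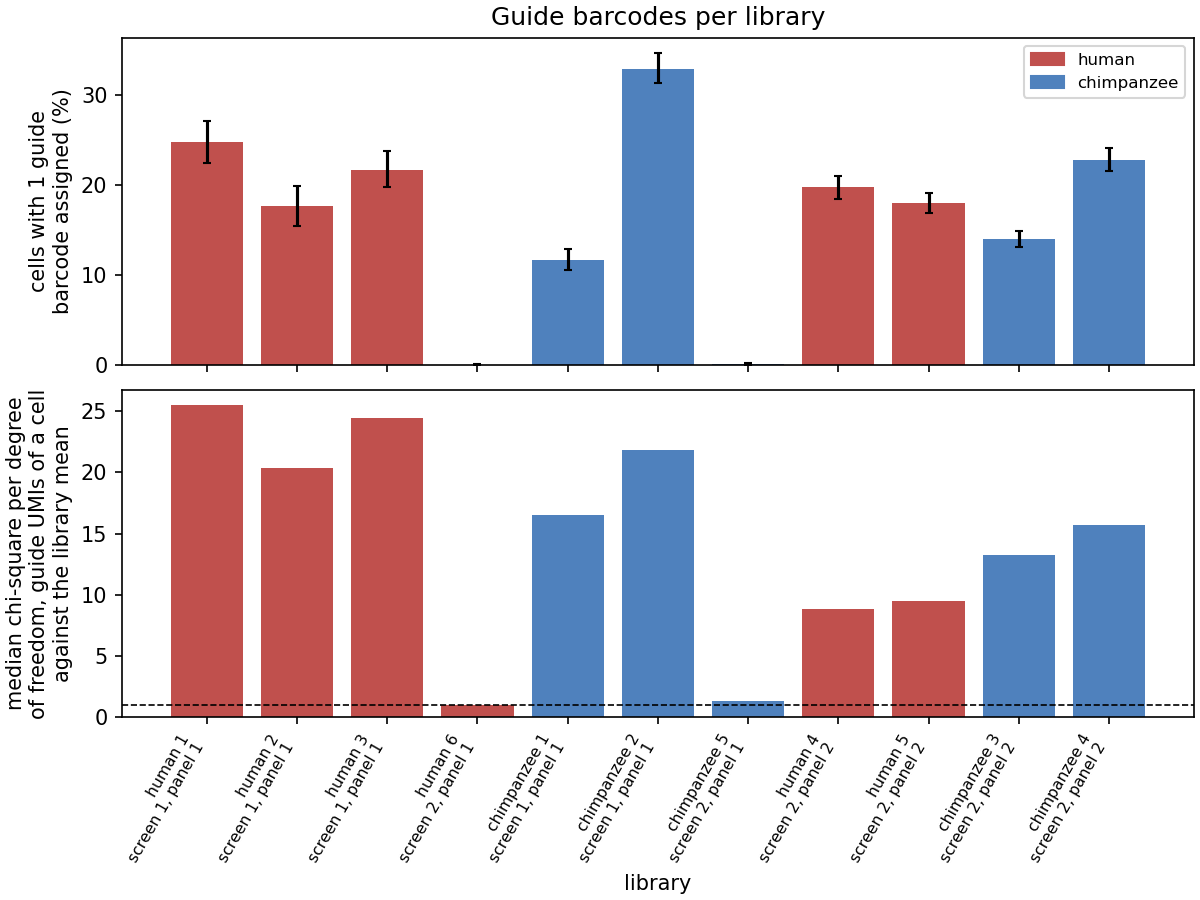
Share of cells with 1 guide barcode assigned (top, percent, with 95% exact intervals) and how far the guide UMIs of the median cell depart from the library's mean (bottom, chi-square per degree of freedom after thinning to 100 UMIs, dashed line at 1). Human 6 (1.02) and chimpanzee 5 (1.31) lie near the line, and the other 9 libraries between 8.85 and 25.5.

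In the pooled fits of human neurons, under the first assignment rule described, no guide barcode changed a gene of the 10 tested past the threshold. Some joint fits and some other assignment rules, given below, did give calls. In the pooled fits 0 of 202 pairs of barcode and gene passed by edgeR, with 14 at an unadjusted level of 0.05. By DESeq2 0 passed, with 5 at that level. The pairs with the smallest p involved TENM3, which was higher in cells with SplintRbar14 (0.11 ± 0.02, higher in 5 of 5 libraries, adjusted p = 0.248), and BAZ1A. BAZ1A had a log2 ratio of 0.32 ± 0.10 with Brainbar4 (adjusted p = 0.248), 0.23 ± 0.07 with SplintRbar20 (adjusted p = 0.299) and -0.27 ± 0.09 with Brainbar8 (adjusted p = 0.424), each in the same direction in 4 of 5 libraries. NPAS3 had -0.19 ± 0.06 with SplintRbar14 (lower in 5 of 5, adjusted p = 0.641).

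In the pooled fits of chimpanzee neurons 24 barcodes could be tested, each for the 7 genes of both panels. Of these pairs 0 passed by edgeR (14 at an unadjusted level of 0.05) and 0 by DESeq2 (13). NPAS3 made up 4 of the 5 pairs with the smallest p. It had a log2 ratio of 0.14 ± 0.03 with SplintRbar27 (higher in 4 of 4 libraries, adjusted p = 0.0682), -0.68 ± 0.17 with SplintRbar30 (lower in 3 of 3, adjusted p = 0.122), -0.20 ± 0.06 with SplintRbar22 and 0.17 ± 0.04 with Brainbar5 (adjusted p = 0.257 for both). AKAP6 had -0.18 ± 0.06 with SplintRbar22 (lower in 4 of 4, adjusted p = 0.257). By the newer edgeR default, NPAS3 passed with SplintRbar27 (adjusted p = 0.0171) and SplintRbar30 (adjusted p = 0.0389), as did AKAP6 with Brainbar3 (adjusted p = 0.00656). Leaving out 1 library gave 0 to 4 calls by the method used. When every barcode with 5 UMIs counted, so that a cell could hold several, 84 of 277 pairs passed in human and 20 of 277 in chimpanzee neurons. With no barcode matched to a control, an effect common to all barcodes could not be seen.

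Whether a guide acted differently in the species was tested as an interaction. It passed for AKAP6 with SplintRbar12 by edgeR, where the human effect lay below the chimpanzee effect by -0.36 ± 0.09 on the log2 scale (adjusted p = 0.0366). It was the 1 of 140 pairs that passed, with 7 at an unadjusted level of 0.05, and by DESeq2 0 passed (12 at that level). For BAZ1A with Brainbar4 the difference was 0.42 ± 0.16 (adjusted p = 0.703), and for NPAS3 with SplintRbar27 -0.15 ± 0.07 (adjusted p = 0.703). The AKAP6 call ended without any 1 of human 1 to 4 or of the 4 chimpanzee libraries used, and its value was 0.048 with the looser assignment of 2 UMIs and 50%. Without chimpanzee 2 another pair passed, NPAS3 with SplintRbar22 (0.42 ± 0.10, adjusted p = 0.0103), named after its value was seen.

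Joint fits per panel brought in the genes of panel 2. In the human libraries of panel 2, BAZ1A was lower in cells with SplintRbar28 (-1.04 ± 0.20), SplintRbar26 (-0.89 ± 0.17) and SplintRbar27 (-0.71 ± 0.18) than over the other barcodes. It was higher with Brainbar4 (0.70 ± 0.15), Brainbar1 (0.64 ± 0.16) and SplintRbar13 (0.57 ± 0.16). For Brainbar4 the fitted value lay above the log2 ratio of BAZ1A's share of UMIs in either library. This ratio was 0.65 in human 4 (12 cells, 1 of them with 25.4% of the UMIs) and 0.20 in human 5 (47 cells). For Brainbar1 it was 0.45 and 0.44. For SplintRbar28 it was -0.84 in human 4 (34 cells) and -1.46 in human 5 (9 cells, 1 of them with 36.4% of the 22 BAZ1A UMIs). ONECUT2 was lower with Brainbar1 (-1.43 ± 0.29), NRSN2, a neuronal membrane protein, lower with Brainbar3 (-0.65 ± 0.18), PLXNC1 higher with SplintRbar26 (0.51 ± 0.13) and AKAP6 higher with SplintRbar24 (0.32 ± 0.09). These 10 of 525 pairs passed by edgeR (adjusted p from 0.00309 to 0.0483), with 71 at an unadjusted level of 0.05. In the chimpanzee libraries of panel 2, 1 of 500 passed, NRSN2 with SplintRbar1 (0.76 ± 0.17, adjusted p = 0.0495), and in panel 1 the counts were 0 of 180 in human (8 unadjusted) and 0 of 170 in chimpanzee libraries (18 unadjusted), with no other tool run. In the human libraries of panel 1, BAZ1A had 0.13 ± 0.14 with SplintRbar28, 0.17 ± 0.15 with SplintRbar26, 0.23 ± 0.12 with SplintRbar27 and 0.10 ± 0.14 with Brainbar4, none past the threshold. Each panel 2 fit rests on 2 libraries, so none could be repeated without a library. With the looser assignment 10 of 567 human pairs passed and with barcodes above background 5 of 588, but the genes differed. BAZ1A passed under both with SplintRbar28, SplintRbar26, Brainbar4 and SplintRbar13, with SplintRbar27 only under the looser one (-0.85, against -0.39 above background) and with Brainbar1 under neither (0.39 and 0.17). The calls of ONECUT2 (-0.51 and -0.29), NRSN2 (-0.34 and -0.14), PLXNC1 (0.36 and 0.23) and AKAP6 (0.16 and 0.040) were lost under both.

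**Figure D4:**
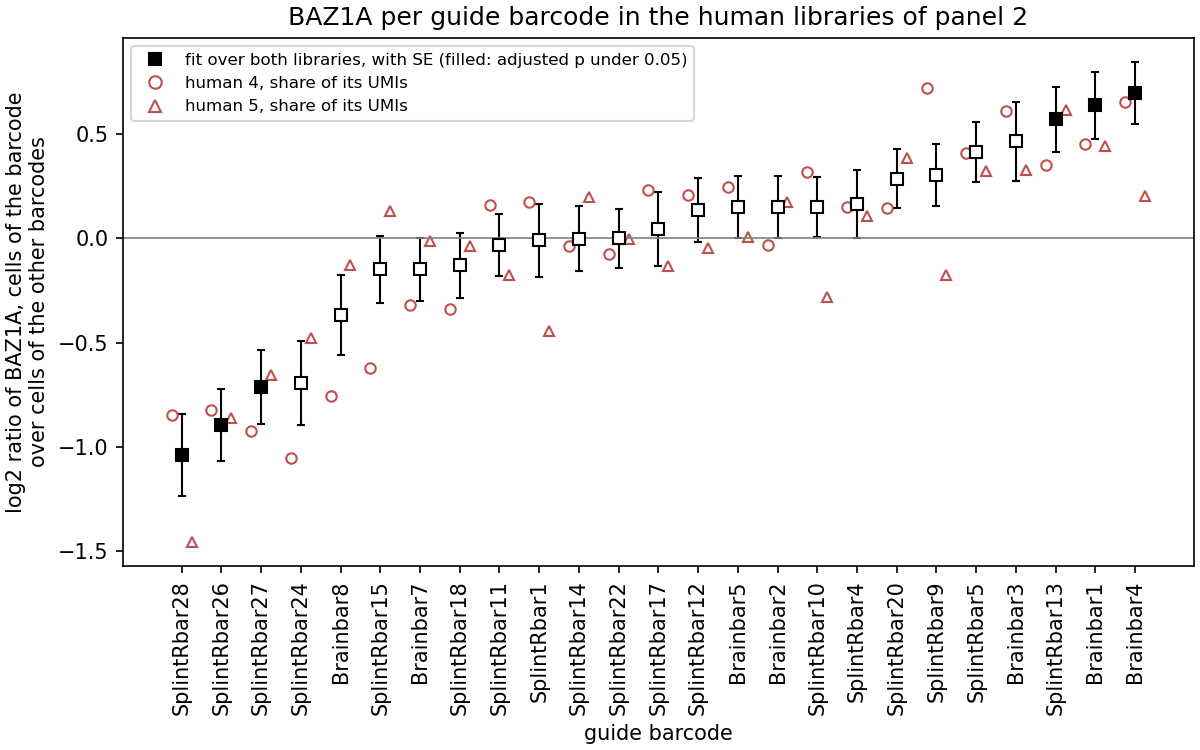
Log2 ratio of BAZ1A between cells of each guide barcode and those of the other barcodes in human 4 and human 5, from the joint fit (squares, with SE) and from each library's own share of UMIs (circles and triangles). The fit runs from -1.04 for SplintRbar28 to 0.70 for Brainbar4.

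How often each barcode was recovered was compared between the species, and no barcode passed the test. SplintRbar30 came nearest to a difference, at 0.299% ± 0.437 of assigned cells in human and 2.10% ± 1.54 in chimpanzee libraries (log2 ratio -2.32 ± 0.71, adjusted p = 0.0586). By edgeR 0 of 28 barcodes passed, with 3 at an unadjusted level of 0.05 and no other tool run. Within panel 1 libraries alone 5 of 27 passed, led by SplintRbar24 (3.32% ± 0.985 in human and 0.153% ± 0.216 in chimpanzee libraries, log2 ratio 5.03 ± 1.02), and within panel 2 libraries alone 2 of 28, SplintRbar4 (4.50 ± 1.03) and SplintRbar20 (2.53 ± 0.78). Without chimpanzee 2 the count was 2 and without human 5 it was 1, which was SplintRbar30. No barcode that passed within 1 panel passed within the other. Of those of panel 1, SplintRbar24 had 0.01 in panel 2, and SplintRbar28 (1.75 and -1.69) and SplintRbar13 (-2.50 and 0.85) changed sign. SplintRbar30 (-4.83 and -2.15) and SplintRbar14 (1.66 and 0.64) kept theirs. Of those of panel 2, SplintRbar4 had -0.91 and SplintRbar20 0.12 in panel 1.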

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

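Of the tests in this part, those of guide depth, of chance overlap and of the AKAP6 to NPAS3 ratio were chosen after the results were seen. Among 27 groups of libraries examined for a library far from its group, 4 had one, where chance (about 1 in 20 groups) would give 1.35.

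The median of 567.5 gene UMIs per cell in chimpanzee 1 stood far above the 126 to 244 of the other chimpanzee libraries. TENM3 in human 3 stood at 155.7 normalized UMIs per 1000, against 135 to 140 in the other human libraries, below every chimpanzee library. The effect of SplintRbar12 on AKAP6 differed between the species by -0.36 on the log2 scale, by the interaction test itself. Of 40 splits of the 9 libraries, 7 gave at least 1 call and none more than 1, so chance was not excluded for that call.

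In human 6 only 0.0397% of cells could be assigned a guide barcode (17.6% to 24.7% in the other human libraries), and in chimpanzee 5 the leading barcode held 10% of the median cell's guide UMIs (37.8% to 47.8% in the others). These are the 2 libraries of panel 1 in screen replicate 2. Too few guide UMIs would not give this, since the lower of their medians was 272 per cell, against 204 in human 4. Guide molecules free in solution and captured alike by every droplet stay open: with each cell thinned to 100 guide UMIs, the median chi-square per degree of freedom against the library's mean was 1.02 and 1.31 (at least 8.85 elsewhere), but this restates the flat profiles, and the ratio of the upper to the lower quartile of guide UMIs per cell, 1.51 and 1.64, was not in both below that of every other library (1.58 in human 2). The barcodes' log2 shares of guide UMIs in human 6 correlated at 0.93, 0.98 and 0.96 with those in human 1, 2 and 3. With human 4 and 5, of its own screen replicate, the correlations were 0.44 and 0.46. Chimpanzee 5 correlated at 0.97 and 0.93 with chimpanzee 1 and 2, and at 0.49 and 0.40 with chimpanzee 3 and 4. Both libraries thus resembled screen replicate 1 in their barcode shares, and why was not tested. No biological explanation was tested.

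Cell barcodes also recurred between libraries of screen replicate 2, where human 4, human 5 and chimpanzee 3 shared at least 995 barcodes per pair, 880 of them in all 3, where at most 1.60 were expected by chance. Chimpanzee 4 and 5 shared 1436, and human 6 shared 400 with chimpanzee 5 and 234 with chimpanzee 4, while pairs across screen replicates shared at most 4. Reads assigned to the wrong library would carry the other species' profile, but in chimpanzee 3 the AKAP6 to NPAS3 ratio was 0.466 in cells with a shared barcode and 0.462 in the rest, while in human 4 (1.88 and 2.32) and human 5 (2.11 and 2.37) shared barcodes lay 13.2% and 7.10% of the way to chimpanzee 3 on a log scale, and those shared by human 6 with chimpanzee 4 or 5 lay at most 10.8% of the way (3.40% in human 6, 3.61% in chimpanzee 4), which argues against reads of the other species as the whole cause and leaves a small part, and exchange between libraries of the same species, open. Free RNA in droplets without a cell may account for part of it: shared barcodes had flatter gene profiles, but the highest of the 3 chi-square ratios, 0.861, missed the bound of 0.8 set before it was computed, which keeps this open. Only 0.170% to 0.930% of these cells had a guide barcode assigned, against 17.2% to 28.2% of the rest, and no biological explanation was tested.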

How the results depend on the processing

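The panel term, fits without human 6 and chimpanzee 5, own cell barcodes, totals without GAPDH, background-based cells and assignment, panels alone for barcode shares, the newer edgeR default and joint fits were chosen after the data were seen. Unless a cause is given, the cause of a change was not tested. The 14 species differences numbered 12 to 17, apart from 0 by edgeR with GAPDH as library size (3 unadjusted), 7 of 10 with screen-replicate sums and 5 of 10 in screen replicate 1 (fewer genes). With GAPDH left out of the totals 9 were higher and 8 lower, against 9 and 5. PSMA6 (0.27 ± 0.22) did not pass in screen replicate 1, AKAP6 (0.89 ± 0.39) in the sums and BAZ1A (-0.54 ± 0.25) in cells above background. DAZL (0.80 ± 0.39) and SRXN1 (0.87 ± 0.39) did not pass without TMM. PSMA6 lost much of its size and the others mainly precision. Screen replicate 1 was fitted relative to all genes of panel 1, however. On that scale PSMA6 had 0.27 ± 0.15 over all panel 1 libraries too, so its smaller ratio came with the changed scale. PUM2 passed in 9 alternatives, RHOB in 4, SCRT2 in 2 and TBC1D5 in 1. The median over genes moved by 0.10 with GAPDH scaling and with equal weight per cell and -0.11 in cells above background. It moved by -0.14 in screen replicate 1, where the scale was all genes of panel 1. GAPDH reversed without human 4 (-0.53) and was 0.63 without human 5.

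Guide effects in chimpanzee neurons numbered 1 with 2 UMIs and 50%, 20 with every barcode of 5 UMIs, 2 without TMM, 1 with at least 20 cells and 3 by the newer default, in place of 0, and human ones 84 with every barcode and 2 above background. A minimum of 5 UMIs per barcode takes in background, so the counts with every barcode were not read as guide effects. The interaction, 1 call, numbered 3 other pairs with 2 UMIs and 50% (AKAP6 with SplintRbar12 then at 0.048) and 2 with at least 2 cells. It numbered 0 with 10 UMIs and 90%, every barcode, no TMM, DESeq2 size factors, DESeq2's test, 20 cells, barcodes above background and the newer default (0, 14, 10, 10, 12, 4, 17 and 13 unadjusted). In the joint fits, human panel 1 gave 8 above background and 1 by the newer default in place of 0. Human panel 2 gave 5 above background in place of 10, and 3 higher and 9 lower without TMM, or 4 and 8 without GAPDH, in place of 5 and 5. Chimpanzee panel 1 gave 2 with 2 UMIs and 50% and 4 above background in place of 0, and panel 2 gave 0 with 2 UMIs and 50%, above background and by the newer default in place of 1 (23, 22 and 22 unadjusted). Barcode shares gave 1 call with a panel term, 5 in panel 1 alone and 2 in panel 2 alone, in place of 0.

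Leaving out 1 library gave 14 to 17 species differences, 0 guide effects in human (6 to 14 unadjusted) and 0 to 4 in chimpanzee neurons (1 without chimpanzee 2, 2 without chimpanzee 3, 4 without chimpanzee 4), 0 to 1 interactions (0 without any of human 1 to 4 or chimpanzee 1, 3 and 4, and without chimpanzee 2 another pair), 0 to 2 barcode shares (2 without chimpanzee 2, 1 without human 5) and 0 in the human panel 1 joint fit. UMIs per cell differed by -0.30 to 0.24 and cells per library by -1791 to -519, none past the threshold.

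Libraries of the species share only screen replicate numbers, whose deviations correlated at 0.68 over the 7 genes of both panels and 0.34 over panel 1, with 2 numbers. With this replicate block there were 15 species differences, 0 guide effects in either species, 0 interactions by edgeR (8, 5 and 1 unadjusted), 1 barcode share, and exact p of 0.835 for UMIs per cell and 0.25 for cells per library.

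Not run were the preset pairs, controls as a reference class, guide fits in screen replicate 2 or, in chimpanzee, screen replicate 1 (under 3 libraries), sums or GAPDH scaling for genes of the other panel, joint fits of 2 libraries without 1, and the newer default for barcode shares over all libraries. The number of cells limits what can be tested: a minimum of 20 cells per class left 52 pairs in human neurons, against 202 with 5.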

Other observations

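The tests in this part of BTG1 levels, of correlation across cells, of BAZ1A in both panels and of the joint fits were chosen after the results were seen. Genes of the same stretch of chromosome, relative to all genes of the fit, differed between the species in opposite directions. On chromosome 14, AKAP6 (0.98) and NPAS3 (-0.60) lie next to each other among the measured genes, as do BAZ1A (-0.59) and PSMA6 (0.51), although PSMA6 did not pass within either panel. On chromosome 12, BTG1 (-1.75) lies beside SOCS2 (1.21) and PLXNC1 (0.83). None of these 7 genes changed sign under an alternative.

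BAZ1A ran against 4 of the genes higher in human neurons across single cells. In human 4 and 5, over 1032 cells of barcodes with no BAZ1A call and thinned to 60 UMIs outside GAPDH, the counts of BAZ1A and of AKAP6, PLXNC1, SOCS2 and ONECUT2 together were correlated at -0.55. Cells drawn from 1 common profile gave -0.16 on average (-0.23 to -0.08 over 100 draws). In chimpanzee 3 and 4 the same values were -0.36 over 976 cells, and -0.11. With counts taken as deviations from the mean of the cell's library and barcode, the correlation was -0.54 over 1021 human cells (-0.16 for drawn cells) and -0.36 over 964 chimpanzee cells (-0.11). Taken singly in the human cells, 4 of the 9 genes higher in human neurons lay below every draw (AKAP6 -0.36, ONECUT2 -0.41, PLXNC1 -0.28 and SOCS2 -0.13), but 3 lay above (ARHGAP5 0.13, BHLHE40 0.07 and PSMA6 0.09). The 5 other genes together were at 0.15 (-0.13 for drawn cells), so the opposition does not hold for the genes higher in human neurons as a whole. It is not particular to BAZ1A either. Within library and barcode, BTG1 and GLI2 together correlated with the sum of AKAP6, PLXNC1, SOCS2 and ONECUT2 at -0.26 in human cells (-0.12 for drawn cells). In chimpanzee cells this was -0.24 (-0.12 for drawn cells). With a fixed total per cell, spread of an abundant group between cells alone lowers other genes.

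In the human libraries of panel 2, 10 pairs of barcode and gene passed, 6 of them of BAZ1A, and shuffling barcode names within libraries gave as many in 1 of 100 cases, the real one, with 3 the highest other, so chance is excluded for their number. The depth of a barcode's cells was not ordered as BAZ1A was, which argues against depth (Spearman's rho 0.11, permutation p = 0.604, 25 barcodes). Chimpanzee cells among the human cells would raise BTG1 and GLI2 with BAZ1A (rho 0.57, permutation p = 0.00350) and lower AKAP6, BHLHE40, SOCS2 and PLXNC1 (rho -0.74, permutation p = 8.00e-05), but in cells of the 3 barcodes with higher BAZ1A, BTG1 stood at 27.1 per 1000 UMIs outside GAPDH, against 25.6 with the 3 lower ones and 73.0 in chimpanzee cells, while BAZ1A itself reached 93.9 against 84.1 in chimpanzee cells, which excludes them as the whole cause. A candidate explanation, as a hypothesis, is that the barcodes hold human cell states in different shares. Across cells of other barcodes BAZ1A and the sum of AKAP6, PLXNC1, SOCS2 and ONECUT2 oppose each other (-0.55, and -0.54 within library and barcode). BHLHE40 does not join them. BTG1 and GLI2 oppose that sum too (-0.26 within library and barcode, against -0.12 for drawn cells), so the opposition is not particular to BAZ1A and does not decide for the hypothesis. Material of the other species would make the excess covariance of BTG1 and GLI2 with that sum 2.99 times that of BAZ1A. In human cells it was 0.262 times (95% bootstrap interval 0.179 to 0.357). That excludes such material as the whole cause in human cells, but a small part mixed with other sources stays open. In chimpanzee cells it was 0.659 times (0.452 to 0.903). That argues against such material as the whole cause there, but the interval missed the stricter bound set before it was computed, so a part stays open. A guide effect alike in human libraries of both panels is argued against, since the 4 called barcodes also fitted in panel 1 averaged -0.10 ± 0.07 there with the sign of panel 2, against 0.84 ± 0.09 in panel 2 (all barcodes, rho -0.29, permutation p = 0.246), but panel 1 was fitted in screen replicate 1 and panel 2 in screen replicate 2, and an effect in screen replicate 2 alone could not be told apart (between the species rho 0.25, permutation p = 0.259; the barcodes have no map to guides).

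In human 4, 1712 of 3825 cells had over 80% of their gene UMIs from GAPDH, against 9 in human 5, 2 in chimpanzee 3 and 7 in chimpanzee 4. Of those 1712 cells 0.526% had a guide barcode assigned, and 35.3% of the others did.

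The libraries were split in 100 ways into groups of 6 and 5 that kept the panels balanced. The real split alone gave 14 species differences, and the highest other gave 13. If libraries count as separate units, chance is thus excluded for their number as a whole. The labels do not say that libraries of 1 screen replicate are separate cultures, and 2 screen replicates allow too few splits to exclude chance at that level. That other split left 1 human library in the group of 6 and is thus nearly the real one mirrored. Some splits with 3 human libraries in the group of 6 still gave 8 calls. The 2 and 2 libraries of panel 2 allow few arrangements, so the splits cannot exclude chance for the genes of panel 2 alone. For guide effects in human and chimpanzee neurons (0 calls each by edgeR and DESeq2, 14 each unadjusted by edgeR, 5 and 13 by DESeq2), 16 and 8 exchanges of guide and other cells are too few to give a share under 0.05, and the highest others were 0 and 1. Where edgeR called 0, each of the 100 splits or shuffles must give at least as many, so they decide nothing: this holds for barcode shares between species (3 unadjusted, highest other split 3) and for the joint fits of panel 1 in human (8 unadjusted, highest other 2) and in chimpanzee libraries (18 unadjusted, highest other 2). For panel 2 in chimpanzee, with 1 call, 30 of 100 shuffles gave at least as many (highest other 4), so chance is not excluded there.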
